A study of Homo sapiens with 24 samples.

How the data were processed

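RNA of HepG2 cells, an established human liver carcinoma line, was measured on 24 spotted arrays with 2 channels each. Per the labels, RNA of cells treated with the ginkgo extract GBE50 (200 µg/mL) or with lovastatin (0.5 µM) was in the Cy3 (green) channel, and a mixture of control RNA of the same time point was in the Cy5 (red) channel. Control cells had received 0.1% DMSO as vehicle, which the series text states for most time points. Each drug was sampled at 2, 6, 12 and 24 h, which gives 8 groups of 3 arrays, numbered 1 to 3 in the sample titles. No array had the dyes exchanged, and no control RNA was hybridised as a sample of its own.

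The deposited value table holds 1 value per spot and array. Per the labels' protocols, the authors subtracted the background, applied LOWESS normalisation and took the logarithm of red over green. The base, scale and direction were checked against the scanner files. Against log2 of net red over net green, over spots with a net signal above 1000 in both channels, the deposited log2 values had slopes of 0.94 to 1.00 on the 24 arrays, so they are log2 ratios of red over green. Over all readable spots with a value the correlation was 0.79 to 0.99. The medians of the 24 columns lay between -0.006 and 0.034. Each value was multiplied by -1, so that all ratios printed here are treated over control. The direction rests on the dyes given in the labels, since no spot of known gene could check it.

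The 48 scanner files hold spot intensity values of 1 channel each, made with ImaGene (version 5.1 per the file headers, version 4.2 per the labels), as the authors deposited them. In 41 of these files the text was intact only up to some line and scrambled after it. Both channels could be read in full on 1 array (GBE50, 24 h, replicate 3), and the leading spots readable in both channels numbered 667 on the array with fewest. The processing planned before the data were examined started from the scanner files (normexp background correction with an offset of 50, then loess). It could not be run on the whole arrays. The deposited log2 table, planned as an alternative, therefore became the source of all results. The planned processing was run on the 1293 tested spots that could be read on at least 2 arrays of every group. These are leading spots, so they are not a sample of the whole array. On readable spots, a blank in the value table followed the signal: 99.1% to 100% of pairs of a valued and a blank unflagged spot were ordered by the net median of the brighter channel. The blanks therefore act as a filter on dim spots.

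Spot names in the files are positions (sub-grid row and column, then row and column), and the files do not pair them with genes. No gene is named for that reason, and the gene lists fixed before the data were examined were not tested. The rule for named genes, fixed earlier, took the 3 highest and 3 lowest ratios of each comparison. Without gene names it was narrowed, before any spot was looked at by name, to the highest and the lowest ratio at 24 h against control for each drug, among spots past the threshold with a value of the same sign on all 3 arrays.

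Of 15552 spots, the 10061 with a value on at least 2 of the 3 arrays in each of the 8 groups were tested. This filter was chosen after the files were opened and before any test. One linear model with a mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 16 residual and 3.72 prior degrees of freedom). Every test was two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The group mean was tested against 0 for treated against control. Because the control is a single reference RNA on each array, this leaves out the spread of the control, and a dye effect that is fixed to a spot enters the ratio. The dye effect cancels in the difference between drugs at a time. The control cancels there only if 1 control mixture served both drugs, which the labels do not state. The interaction (the difference between the drugs in the change from 2 h to 24 h) was added after the files were opened. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

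Signal variances and covariances over spots were computed from pairs of different arrays, so that array noise does not enter, with a jackknife standard error over the 48 sub-grids. Spots are not independent replicates. Slide numbers were read from the names of the scanner files and cut into 3 runs wherever they jumped by more than 10. The runs are thus inferred. The image analysis falls into 10 days, by the day of the month in the file headers. Run 1 holds GBE50 at 24 h and all lovastatin arrays, and runs 2 and 3 hold the other GBE50 arrays. No image day holds arrays of both drugs. Each group except GBE50 at 6 h lies in 1 run. A random block for run or day can therefore remove little of a batch difference between the drugs.

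Same-numbered arrays of different groups did not deviate together. Over 84 pairs of groups and numbers, the correlation of the deviations averaged 0.003, and 9 pairs were above 0.1. The numbers were therefore not taken to pair the arrays. At most 0.01% of values were identical between arrays of a group, so no array was counted as a repeat of another.

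The fit was tested on simulated data with the observed residual spread, the observed blanks and 200 changed spots among 10061. For GBE50 against control at 24 h, 68% of spots changed 1.2-fold and 100% of those changed 1.5-fold were recovered. For the difference between drugs at 24 h, 32% of spots changed 1.2-fold, 84% of those changed 1.5-fold and 98% of those changed 2-fold were recovered. In each simulation 12 unchanged spots were called. The noise was drawn independently, with the spread shuffled over spots and no shared control error, dye effect or batch. In the data, 52.45% (lovastatin at 2 h) to 70.64% (lovastatin at 24 h) of spots were called against control. The simulated shares need not hold for the real arrays. Alternatives covered scaling and centring, the filter, the sub-grids, the batches, the replicate number as a block, array weights, a 2-fold minimum and leaving out arrays.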

Results

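Transcript levels in HepG2 cells were measured after 2, 6, 12 and 24 h of treatment with GBE50, a ginkgo leaf extract, or with lovastatin, a statin that inhibits HMG-CoA reductase, the rate-limiting enzyme of cholesterol synthesis. Each of the 24 arrays compared 1 treated sample with the control RNA of its time point, with 3 arrays in each of 8 groups. The arrays carried 15552 spots, of which 10124 to 12510 had a deposited value on an array. A value was present on all 24 arrays at 8346 spots and on none at 1813. Over the readable spots, the median signal of an array was 478 to 850 in the green channel, against a median background of 245.5 to 347, and 437 to 1050 in the red channel, against 177.5 to 246.5. Arrays of 1 group correlated at 0.83 to 0.96 over spots, and the lowest correlation between any 2 arrays was 0.35. The median SD between the 3 arrays of a group was 0.06 to 0.10 on the log2 scale. The files do not pair the spots with genes, so 4 spots are followed by their position.

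The GBE50 arrays against control address which transcripts the extract changed and when. The highest ratio at 24 h was at spot Sr11Sc02R11C09, which was already 5.69-fold above control at 2 h (log2 2.51 ± 0.33, SD, n = 3). Its log2 ratio was 3.04 ± 0.25 at 6 h, 3.47 ± 0.16 at 12 h and 4.00 ± 0.32 at 24 h, the last a 16.0-fold excess (limma adjusted p = 5.08e-16). The lowest ratio at 24 h was at spot Sr12Sc01R08C09. Its log2 ratio was -0.93 ± 0.12 at 2 h, -1.64 ± 0.14 at 6 h, -2.65 ± 0.28 at 12 h and -2.77 ± 0.20 at 24 h, a 6.81-fold deficit (limma adjusted p = 1.31e-15). On the 1 array readable in full, GBE50 at 24 h, the dimmer channel of these spots lay 2.9 (Sr11Sc02R11C09, red) and 2.41 (Sr12Sc01R08C09, green) background SDs above its background, so the size of these ratios rests on a dim channel.

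Under GBE50, 2955 spots were higher and 3187 lower than control at 2 h, 3227 higher and 3571 lower at 6 h, 3409 higher and 3603 lower at 12 h, and 3306 higher and 3759 lower at 24 h, of 10061 tested. Most of these differences were small. The median size among spots past the threshold was 1.25-fold at 2 h and 1.27-fold at 24 h. At least 2-fold differences were found at 258 spots at 2 h, 361 at 6 h, 487 at 12 h and 425 at 24 h, and at 24 h 336 of them were higher and 89 lower. The SD of the GBE50 signal over spots, free of array noise, was 0.38 ± 0.01 (jackknife SE) at 2 h, 0.44 ± 0.01 at 6 h, 0.48 ± 0.01 at 12 h and 0.47 ± 0.01 at 24 h. These counts and SDs include any dye effect fixed to a spot, since the dyes were never exchanged. The SDs also include whatever else the arrays of a group share, such as the control or the slide run. Their standard errors are over sub-grids and do not measure the spread between arrays or cultures.

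The lovastatin arrays address the same question for the statin. Spot Sr04Sc04R13C02, the highest at 24 h, had a log2 ratio of 0.06 ± 0.06 (SD, n = 2) at 2 h, where limma's adjusted p was 0.671. It was 0.56 ± 0.12 at 6 h, 1.73 ± 0.31 at 12 h and 3.58 ± 0.14 at 24 h (n = 3 each), an 11.9-fold excess at 24 h (limma adjusted p = 1.68e-16). Spot Sr10Sc01R11C02, the lowest at 24 h, was below control throughout, with log2 ratios of -2.54 ± 0.09 at 2 h, -2.22 ± 0.02 at 6 h, -3.56 ± 0.01 at 12 h and -2.37 ± 0.26 at 24 h (limma adjusted p = 4.99e-15 at 24 h). On the arrays where Sr04Sc04R13C02 could be read, its red channel lay 0.701 (GBE50, 2 h, replicate 2, where the spot was flagged in both channels) to 9.1 (lovastatin, 12 h, replicate 1) background SDs above background, and none of these was a lovastatin array of 24 h. Both channels of Sr10Sc01R11C02 lay at least 17.9 above theirs on the 2 arrays where it could be read.

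Against control, lovastatin gave 2550 higher and 2727 lower spots at 2 h, 3068 and 3189 at 6 h, 3053 and 3709 at 12 h, and 3280 and 3827 at 24 h. Which direction had more calls depends on the centring of the arrays. With each array centred on its median, the 24 h counts were 3592 higher and 3428 lower under lovastatin, and 3522 and 3496 under GBE50. At least 2-fold differences were found at 140 spots at 2 h, 243 at 6 h, 337 at 12 h and 460 at 24 h. The 2-fold spots at 24 h were 386 higher and 74 lower, while those at 12 h were 163 higher and 174 lower. The SD of the lovastatin signal was 0.32 ± 0.01 (jackknife SE) at 2 h, 0.39 ± 0.01 at 6 h, 0.43 ± 0.01 at 12 h and 0.48 ± 0.01 at 24 h. The same limits apply as for GBE50.

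**Figure D1:**
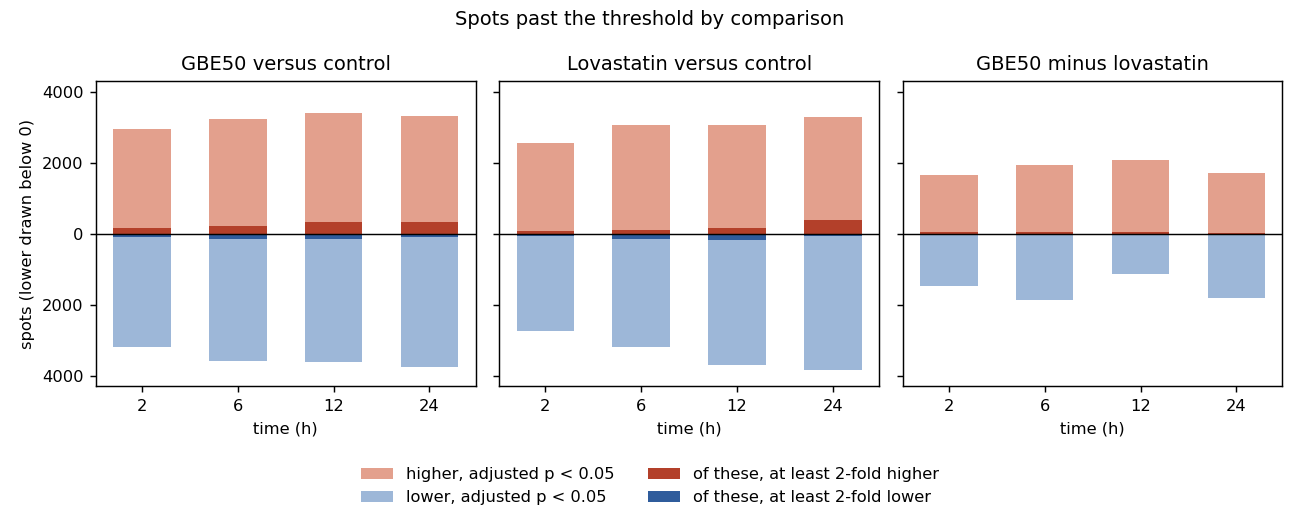
Number of spots past the threshold (limma, adjusted p under 0.05) at each time (h), higher above 0 and lower below 0, for GBE50 against control, lovastatin against control and GBE50 minus lovastatin; dark bars are the part at least 2-fold. The counts against control were lowest for lovastatin at 2 h, with 2550 higher and 2727 lower, and the 2-fold part stayed small in every panel.

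The spots called under the 2 drugs overlapped. At 24 h, 2392 spots were higher under both drugs and 2769 lower under both, where independent lists of these lengths would share 1077.8 and 1429.8. At 2 h the shared spots numbered 1565 higher and 1832 lower, against 748.96 and 863.83. Opposite calls were fewer. At 24 h, 223 spots were higher under GBE50 and lower under lovastatin, and 161 were the reverse. The covariance between the drugs over spots was 0.09 ± 0.01 (jackknife SE) at 2 h, 0.14 ± 0.01 at 6 h, 0.18 ± 0.01 at 12 h and 0.19 ± 0.01 at 24 h. The group means correlated at 0.73 at 2 h and 0.82 at 24 h. Both drugs were read against a control of the same time point, which may have been 1 mixture, and with the same dyes. Part of the overlap may come from these. The lists also share 1 estimate of the spread per spot, so they are not independent. The overlap that the control alone would give could not be simulated, because no array holds a control sample of its own.

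**Figure D2:**
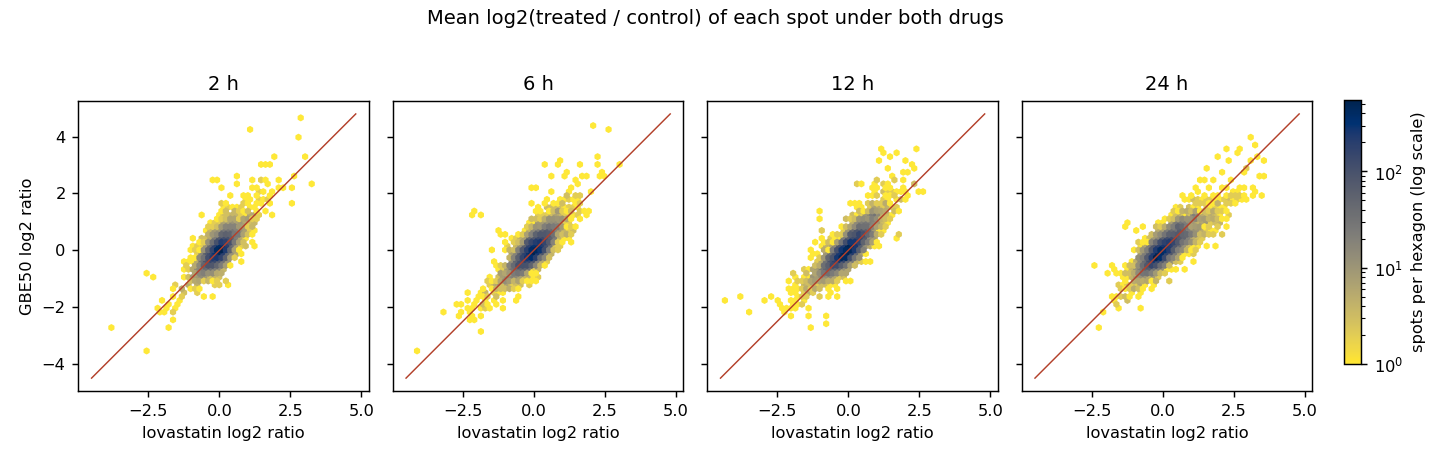
Mean log2(treated / control) of each tested spot under lovastatin (horizontal) and GBE50 (vertical) at each time, as counts of spots per hexagon on a log colour scale; the line marks equal ratios. The cloud lies along the line at every time, with a covariance between the drugs of 0.09 at 2 h and 0.19 at 24 h.

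The direct difference between the drugs asks where the extract and the statin differ, and in it a dye effect fixed to a spot cancels. The control cancels only if 1 control mixture served both drugs at a time, which the labels do not state. At spot Sr11Sc02R11C09, GBE50 exceeded lovastatin by a log2 difference of 2.72 ± 0.18 (SE) at 2 h, 2.72 ± 0.18 at 6 h, 2.29 ± 0.18 at 12 h and 0.92 ± 0.18 at 24 h (limma adjusted p = 0.000454 at 24 h). Spot Sr04Sc04R13C02 had differences of 2.09 ± 0.15 at 2 h and 1.73 ± 0.14 at 12 h, and of -0.36 ± 0.14 at 24 h, where limma's adjusted p was 0.0502. Its difference at 2 h rests in part on the flagged array, and without that array was 2.19 ± 0.16 (limma adjusted p = 2.88e-08). Its 24 h difference crosses the threshold in that fit (limma adjusted p = 0.0446) and with a replicate block (0.0284). Spot Sr12Sc01R08C09 was lower under GBE50 at every time, by a log2 difference of -1.88 ± 0.13 at 12 h and -0.53 ± 0.13 at 24 h. Spot Sr10Sc01R11C02 turned, from -1.03 ± 0.13 at 2 h to 1.84 ± 0.13 at 24 h.

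GBE50 was above lovastatin at 1654 spots and below it at 1486 at 2 h. The counts were 1930 above and 1855 below at 6 h, 2079 above and 1145 below at 12 h, and 1701 above and 1823 below at 24 h. Leaving out replicate 3 of every group, which leaves fewer arrays to test, lowered the totals from 3140, 3785, 3224 and 3524 to 1749, 2336, 1964 and 2092. Averaged over the 4 times, 3057 spots were above and 2724 below. Differences of at least 2-fold were rare, with 57 spots above and 12 below at 2 h, 48 and 9 at 6 h, 53 and 11 at 12 h, 26 and 35 at 24 h, and 30 and 2 in the average. Of the 3524 spots that differed at 24 h, 1492 were called in the same direction under both drugs and differed in size, and 384 were called in opposite directions. A difference at all 4 times was found at 359 spots with GBE50 above and 297 with GBE50 below, where independent lists would give 11.1 and 5.65. The 4 lists share 1 estimate of the spread per spot, so they could exceed this without a lasting difference between the drugs. At 2, 6 and 12 h the drugs lay on different slide runs, so drug and run cannot be told apart there. At 24 h both lay in 1 run, and a fit to the arrays of that run alone gave 1522 spots above and 1621 below. The division into above and below depends on the spots used and on the processing. The 1293 readable spots are leading spots and not a sample of the whole array. On them, the deposited values gave 105 above and 381 below at 24 h, against 1701 and 1823 over all tested spots. Normexp with loess gave 192 and 244 on the readable spots.

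**Figure D3:**
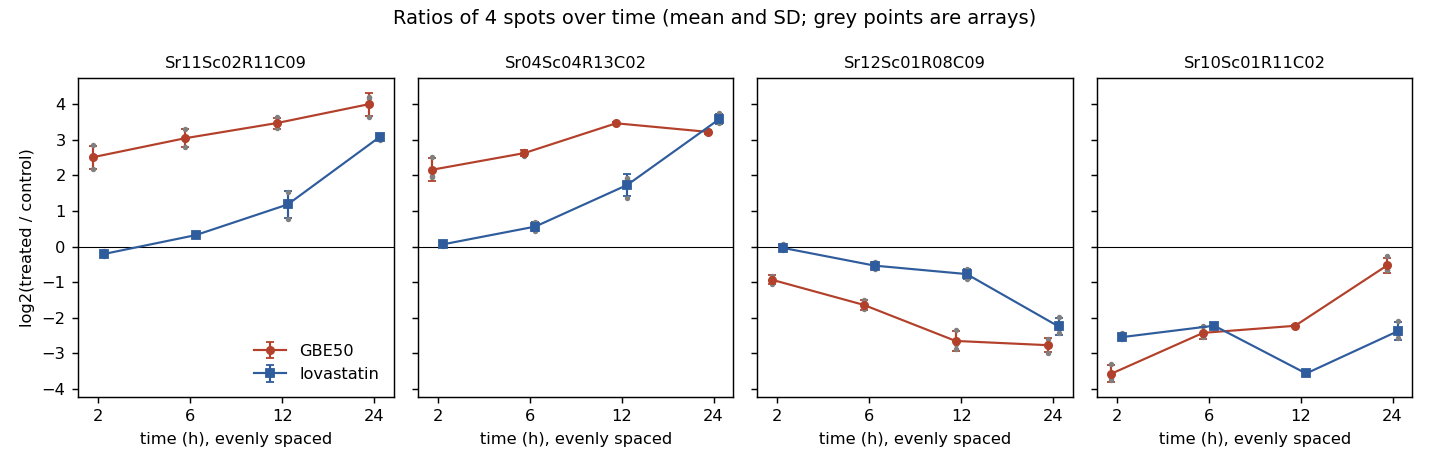
Mean log2(treated / control) with SD at 2, 6, 12 and 24 h (evenly spaced on the axis) for the 4 followed spots, GBE50 in red circles and lovastatin in blue squares, with single arrays as grey points. The lovastatin ratio of Sr11Sc02R11C09 went from -0.21 at 2 h to 3.08 at 24 h, and that of GBE50 from 2.51 to 4.00.

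The change from 2 h to 24 h was compared within each drug. It compares ratios against the controls of 2 different times. The 4 followed spots were chosen by their 24 h ratios, which enter this change, so the choice favours some of their changes and p-values. Spot Sr04Sc04R13C02 rose by a log2 difference of 3.51 ± 0.15 (SE) under lovastatin and of 1.06 ± 0.14 under GBE50. Spot Sr12Sc01R08C09 fell under both, by -2.21 ± 0.13 under lovastatin and -1.84 ± 0.13 under GBE50, and the difference between these changes had a limma adjusted p of 0.16. Spot Sr10Sc01R11C02 rose by 3.04 ± 0.13 under GBE50, while the lovastatin change was 0.17 ± 0.13 (limma adjusted p = 0.264).

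Under GBE50, 2508 spots were higher at 24 h than at 2 h and 2432 lower. Under lovastatin, 2645 were higher and 2706 lower. Over the tested spots, 1585 were higher and 1454 lower under both drugs, where independent lists would share 659.34 and 654.11. The controls of 2 h and 24 h may have been the same for both drugs, which by itself would make these lists agree. They also share 1 estimate of the spread per spot. The division into higher and lower depends on the spots used and on the processing. On the 1293 readable spots, the lovastatin change was higher at 451 and lower at 245 in the deposited values. With normexp and loess it was higher at 355 and lower at 375 of them. The change was at least 2-fold at 263 spots under GBE50 and at 429 under lovastatin, of which 372 were higher. The 2 h and 24 h GBE50 arrays lay on different slide runs, so time and run cannot be told apart for GBE50. All lovastatin arrays lay in 1 run, but no image day held lovastatin arrays of both 2 h and 24 h. Time and image day therefore cannot be told apart for lovastatin.

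**Figure D4:**
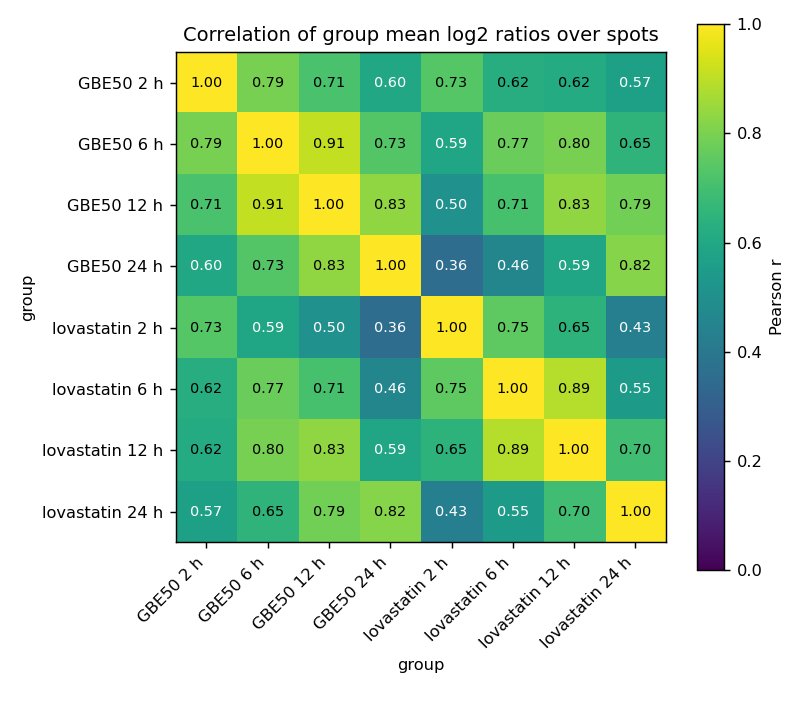
Pearson correlation over the tested spots between the mean log2 ratios of the 8 groups (drug and time on both axes). The lowest value, 0.36, is between GBE50 at 24 h and lovastatin at 2 h, and neighbouring times of 1 drug reach 0.91 (GBE50 at 6 and 12 h).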

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

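The tests of the dye, of the control RNA, of lovastatin alone and of a processing difference common to a drug were chosen after the results they bear on were seen. The interaction was added after the files were opened. The tests of slide position, slide run and array splits were set before, but the slide run explanation for 24 h was narrowed to the 24 h arrays after its value was seen.

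The change from 2 h to 24 h differed between GBE50 and lovastatin at 2488 spots, with the GBE50 change above the lovastatin change at 1146 and below it at 1342 (interaction in limma, adjusted p under 0.05). The count depends on the arrays kept, with 1404 without replicate 2 and 1287 without replicate 3 of every group. A difference between drugs in the same contrast is what drew attention to it. Of 100 drawn splits of the arrays within the 2 h and 24 h times, 1, the real one, reached this count, and the highest other had 1770. These splits exchange the drugs within each time, so they ask whether the drugs differ at either time. They do not test the interaction by itself, and no conclusion on chance is drawn for it. Nor do the labels state that the arrays of a group came from separate cultures, so chance between cultures may not be covered either. On the 1293 readable spots the GBE50 change was above at 70 and below at 257 in the deposited values, and at 142 and 181 with normexp and loess, so no direction is read from this pattern. An effect of lovastatin alone that rises with time stays open. The GBE50 change had a signal variance of 0.144 ± 0.005 (jackknife SE), but it spans different slide runs and controls, which could give it without a response. Slide run stays open, since 0 of the 2 h GBE50 arrays lie in the slide run of the 24 h GBE50 arrays, and run and time cannot be told apart for that drug. A difference in the course of the response, which the design names, also stays open.

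The shared log2 ratios against control were weighed next. A dye effect fixed to each spot would give the same covariance between the drugs at every pair of times. The lowest (GBE50 at 24 h with lovastatin at 2 h) was 0.286 times the highest (both drugs at 24 h), which argues against it as the whole of the shared signal. An offset of whole sub-grids is argued against too, since the covariance at a time kept at least 0.974 of its value after each sub-grid was centred. The sub-grid medians so removed were small, with an SD of 0.0511 at 2 h to 0.0828 at 24 h. A trend within a sub-grid was not tested. The lowest covariance, 0.05368 ± 0.005 (jackknife SE), bounds a part common to all times only if the responses did not covary negatively, which was not tested. Without a dye swap a dye effect may account for all of it. The same-time covariance exceeded that of different times by 0.0364 on average, and a control RNA, if both drugs shared one at a time, and a shared response to treatment cannot be told apart there.

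At 24 h, the 3524 spots that differed between the drugs lie in 1 slide run. Over all tested spots, the differences at 24 h correlated at 0.449 ± 0.018 (jackknife SE) with the mean difference at the 3 other times, which come from other arrays. This argues against the slide run or image day of the 24 h arrays alone. Centring each sub-grid left 3569 spots, which argues against an offset of whole sub-grids as the cause. A trend within a sub-grid was not tested. The division into above and below on the leading readable spots differed from that over all tested spots, so position may still bear on direction. A processing difference common to all arrays of one drug may still contribute, since 0 image days hold arrays of both drugs. Separate control mixtures for the drugs, which the labels do not rule out, were not tested. A difference between the drugs stays open as well.

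For each comparison of 3 arrays with 3, the splits number 10, too few for a share under 0.05, and in each case 1 split, the real one, reached the real count. The real count and the highest other were 3140 and 0 for the drugs at 2 h, 3785 and 0 at 6 h, 3224 and 1 at 12 h, 3524 and 2 at 24 h, 4940 and 5 for 24 h against 2 h under GBE50, and 5351 and 2 under lovastatin. For the average over the 4 times, 1 of 100 splits, the real one, reached 5781, and the highest other had 2032. For this average, that argues against chance among these arrays. At 2, 6 and 12 h drug and slide run cannot be told apart, and a run difference would stand out in these splits as well. Chance between cultures is covered only if the arrays of a group came from separate cultures, which the labels do not state.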

How the results depend on the processing

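All 15 planned counts and the interaction count stayed within 1.5 times under scaling, no filter and array weights. The same held for a value on all 24 arrays and array or sub-grid centring (all chosen after seeing the data). Slide run or image day as a random block kept them too, but can remove little of a batch difference between drugs. The direction with more calls turned in 5 of the 16 counts with each array centred on its median and in 6 with sub-grid centring. Lovastatin against control at 24 h went from 3280 higher and 3827 lower to 3592 and 3428 and to 3619 and 3486. With the replicate block GBE50 against control at 2 h gave 6118 spots and the drugs at 24 h 3485, all counts stayed within 1.5 times, and of 57 calls at the 4 followed spots 0 were lost and 1 was gained (Sr04Sc04R13C02 between the drugs at 24 h, adjusted p 0.0284). Same-numbered arrays correlated at -0.20 to 0.26 in their deviations, and 12 of 24 arrays were closest to their own number. With a minimum of 2-fold, by construction, GBE50 against control kept 258, 361, 487 and 425 spots at 2, 6, 12 and 24 h, lovastatin against control 140, 243, 337 and 460, GBE50 minus lovastatin 69, 57, 64 and 61, their average 32, the change from 2 h to 24 h 263 for GBE50 and 429 for lovastatin, and the interaction 167. Leaving out replicates or single arrays, which leaves fewer to test, moved 5 counts by over 1.5 times. Each moved only where all groups lost the same replicate. The ranges were 1749 to 2914 for the drugs at 2 h, 2336 to 3366 at 6 h, 1964 to 3027 at 12 h, 2092 to 3363 at 24 h and 1287 to 2546 for the interaction. On the 1293 readable spots, the 16 counts under normexp and loess, no background subtraction, plain subtraction, Signal Median, median centring, print-tip loess and a stricter use of flags were 0.746 to 1.42 times those from the deposited values. The higher part of the calls moved by over 10 points in 5 of 16 counts with normexp and loess, 8 without subtraction and 10 with median centring, and in 4 with deposited values centred on each array's readable spots (chosen after seeing the data). GBE50 minus lovastatin at 24 h had 105 higher and 381 lower as deposited, 159 and 242 when so centred, and 202 and 174 without subtraction. Lovastatin against control at 24 h had 536 and 378 as deposited and 450 and 526 with normexp and loess. The scanner settings centre on the readable spots, which accounts for part of this. Median centring without loess turned 222 of 8105 calls shared with the deposited values, and normexp with loess 4 of 8942. These settings, and a filter on spots above background in both channels on all arrays, were not run on the whole arrays, and the gene list tests were not run. Signal over background limits 3 of the 4 followed spots, whose dimmer channel lay 2.41 to 2.9 background SDs above background on the array readable in full, and for Sr04Sc04R13C02 0.701 on a flagged 2 h GBE50 array. Without that array (chosen after seeing the data) its 2 h difference between the drugs was 2.191, and its 24 h difference gained a call (adjusted p 0.0446).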

Other observations

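The tests in this part were chosen after the results were seen.

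Lovastatin at a later time resembled GBE50 at an earlier time more than the reverse. The array-noise-corrected correlation of GBE50 at 12 h with lovastatin at 24 h was 0.80, and that of lovastatin at 12 h with GBE50 at 24 h was 0.61. For GBE50 at 6 h with lovastatin at 12 h it was 0.82, and for lovastatin at 6 h with GBE50 at 12 h it was 0.72. All 6 pairs of times went this way, with differences of 0.03 to 0.22 and a mean of 0.146 ± 0.011 (jackknife SE). Among the 3 pairs without 24 h the mean difference was 0.09 ± 0.01. A candidate explanation is that the lovastatin changes follow the GBE50 changes in time, and the sign of this mean is what it needs. Of 3174 spots called under lovastatin at 24 h but not at 2 h, 41.2% were already called in the same direction under GBE50 at 2 h and 10.5% in the opposite one. Of 2405 spots called under GBE50 at 24 h but not at 2 h, 17.9% were called in the same direction under lovastatin at 2 h and 20.7% in the opposite one. GBE50 also had more calls at 2 h, 6142 against 5277, which adds to the first share. The 4 followed spots were chosen by their ratios at 24 h, 2 of them under GBE50, which favours this order at those spots, so they lend it no support. At Sr10Sc01R11C02 the GBE50 ratio rose by 3.04 from 2 h to 24 h while the lovastatin change was 0.17. That comparison skips the lovastatin log2 ratio of -3.56 at 12 h, which was near the GBE50 ratio of -3.57 at 2 h. It therefore does not decide the order at this spot. The GBE50 arrays of 2, 6 and 12 h lay on other slide runs than GBE50 at 24 h and lovastatin, so run may bear on these correlations. Its effect on them was not tested. The standard error is over sub-grids of the same arrays and leaves out the spread between arrays, controls and cultures. The 6 pairs reuse the same 8 groups. The hypothesis was found and tested on the same arrays, and nothing in the labels says that the doses were matched for strength.

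In all 8 groups 706 spots were higher than control and 709 lower, and since all arrays share the dye orientation, and may share controls within a time, a dye effect fixed to a spot could give such lists as well as a response. The lowest covariance between the drugs over the pairs of times, 0.05368, does not divide them. At least 2-fold in each of the 8 groups were 30 of the higher spots and 0 of the lower ones. At 197 spots no group differed from control.

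On the array readable in full, GBE50 at 24 h replicate 3, 4071 spots were blank in the value table without a flag. Of these, 2850 (70.0%) were more than 2 background SDs above background in both channels. Over the readable part of each array this share was 4.11% to 73.8%, so this array lies near the top of the range.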
